A study of Mus musculus with 10 samples.

How the data were processed

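Tumours of BBN963 cells in mice, 5 ATM-WT and 5 ATM-KO, were harvested at a stated size, and part of each was frozen, per the labels. A sequencing company extracted the RNA and made the libraries, per the labels' protocols. The authors deposited one table of normalized counts, a signal that is never negative, for 23086 gene symbols in 10 columns. Per the submitters' processing notes, STAR, Salmon and DESeq2 were used by the authors. Their versions, roles and settings, the genome build and the annotation are not given in the sources used here. Columns name the genotype and a library number that the sample labels do not carry, so they were assigned to groups only.

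Each library's low values were searched for the worth of 1 read. Only 58.7% to 68.9% of values up to 20 reads lay within 0.05 of a whole multiple, so whole reads could not be recovered and no count model was run. Dividing each total by that worth gave estimated depths of 8.82 to 28.3 M (mega) reads. Shallower libraries have larger counting error in low genes. Symbols altered by R on export were restored, and 21634 of 23086 were given one chromosome from GENCODE M21. No coordinates are given because the authors' build is unknown.

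Genes with a mean of at least 10 over the 10 libraries were tested on log2(value + 1) with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend), with Benjamini-Hochberg adjustment and a threshold of 0.05. Lists of genes fixed before the data were examined (42 lists, 837 of 914 genes tested) and chromosomes were tested with limma's camera at a preset correlation of 0.01, adjusted over lists or chromosomes. Named genes are Atm, the 12 largest rises and 12 largest falls among genes past the threshold with a mean of at least 50 and an assigned name, and up to 4 members per list with the smallest p. Of these, 3 genes are not reported here. Exact permutation tests are two-sided over all splits of 5 against 5. Tables were handled in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.

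The procedure was tested on simulated data for ATM-KO against ATM-WT (16301 genes, 200 changed by 2-fold or 4-fold). An added gene list and the genes of chromosome 6 were shifted besides. The procedure recovered 51% of 2-fold and 85% of 4-fold changes, with 0 of the wrong sign and 21 of 15276 unchanged genes called. Genes were simulated independently, so list calls were not tested where genes vary together. Alternatives covered the pseudocount, the filter, upper-quartile and quantile scaling, the eBayes settings, sample weights, other list tests and leaving out each library. Leaving out ATM-WT libraries A2 and A4 together, leaving out genes at 0 in one group, and 11 further gene lists were chosen after seeing the data.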

Results

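RNA from 10 mouse tumours grown from BBN963 cells, a urothelial (bladder) carcinoma line, was sequenced, 5 from ATM-WT cells and 5 from ATM-KO cells. ATM is a kinase that signals DNA double-strand breaks, and the one comparison in the design asked how tumours without it differ in their messenger RNA. The deposited table gave normalized counts of 23086 genes, and each library summed to between 20.2 and 22.3 M normalized counts (M, mega). From the spacing of low values, the libraries rested on a rough estimate of 20.6 to 28.3 M reads, except ATM-WT library A2 with 8.82 M. ATM-WT libraries A2 and A4 listed 4824 and 4266 genes at 0, against 2225 to 3602 in the others. A4 also had 164 genes near 1 read, against 451 to 922 in the others. The labels do not say how many knockout clones were used or that each tumour came from a separate animal, so p-values measure only the spread between these samples. Levels below are mean normalized counts ± SD over 5 libraries per group, and log2 fold changes (ATM-KO minus ATM-WT, on the log2(value + 1) scale, which understates changes of low genes) carry ± SE.

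Atm messenger RNA itself did not separate the genotypes. The ATM-WT libraries A1 to A5 held 433, 768, 311, 360.4 and 554 normalized counts, and the ATM-KO libraries A11 to A15 held 659, 409.9, 366, 529.5 and 312. The means were 485 ± 183 and 455 ± 139, a log2 fold change of -0.07 ± 0.26 with an approximate 95% interval from -0.58 to 0.44 (limma adjusted p = 0.85, exact two-sided permutation p = 0.82 over all splits of 5 against 5). A knockout made by a small insertion or deletion need not lower the transcript, and the labels do not say which lesion was made, so this level neither checks nor contradicts the genotype labels.

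The tumours differed widely by genotype. Of 16517 genes tested with limma, 3649 were higher and 4017 lower in ATM-KO, together 46.4% of those tested. Large falls outnumbered large rises, with 928 genes lower and 162 higher by more than 3 on the log2 scale. The values of the groups did not overlap for 5813 genes (35.2%), where chance gives 0.794%. After quantile normalization, which moved the median log2 fold change of all genes from 0.00467 to 0.15, the split was 4514 higher and 3319 lower. The first principal component held 65.3% of the variance and separated the genotypes (exact permutation p = 0.0079, the smallest that all splits can give). Pearson correlations of log2 values were 0.97 to 0.98 among ATM-KO libraries, 0.88 to 0.95 among ATM-WT libraries and 0.76 to 0.86 between groups.

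Most epithelial marker genes were low or listed at 0 in the ATM-KO tumours. The basal keratin gene Krt5 fell from 32455 ± 22351 to 17.01 ± 26.3 (-12.53 ± 1.14, limma adjusted p = 3.43e-06), and Krt6a, a keratin of stratified and wounded epithelium, from 27776 ± 16042 to 4.77 ± 3.63. Krt4 averaged 6201 ± 5857 in ATM-WT and was listed at 0 in every ATM-KO library. Further genes among the largest falls were Mal2 (-11.60 ± 0.44), Krt6b (-11.37 ± 0.68), Cstdc5 (-11.10 ± 0.91), Spink5 (-10.55 ± 0.71), Fxyd3 (-10.24 ± 0.54), Serpinb3a (-10.20 ± 1.04), Gabrp (-10.19 ± 0.59) and Dapl1 (-9.91 ± 0.82), with ATM-WT means of 2287 to 8397 and ATM-KO means of at most 4.11. In the list of basal and squamous urothelial markers, 1 of 25 tested members rose and 23 fell (1 and 23 adjusted over the list alone), with a median of -5.36. The basal list had camera adjusted p = 1.71e-10, and adjusted p = 0.51 with an estimated correlation. Krt17 fell from 6320.1 ± 2416 to 12.98 ± 7.73 and the hemidesmosome integrin Itgb4 from 1708 ± 784 to 53.1 ± 10.4. Among luminal markers, 0 of 21 tested members rose and 18 fell (0 and 18 adjusted over the list alone), with a median of -2.40. The luminal list had camera adjusted p = 1.23e-08, and adjusted p = 0.50 with an estimated correlation. Without the 3 luminal members at 0 in all libraries of one group, the median was -2.31. Among those that fell were the simple-epithelium keratin genes Krt8 (from 10857 ± 4561 to 15.2 ± 10.8), Krt19 (from 10238 ± 4181 to 10.2 ± 3.17) and Krt7 (from 7219 ± 1809 to 21.1 ± 14.8). Of the skin and hair follicle markers 1 of 13 tested members rose and 8 fell (1 and 8 adjusted over the list alone), with a median of -3.08. The skin list had camera adjusted p = 0.011, and adjusted p = 0.56 with an estimated correlation. Without the 1 skin member at 0 in all libraries of one group, the median was -2.43. Krt1, Krt15 and Flg fell, while the lipid desaturase gene Scd1 (from 1345 ± 459.7 to 5379 ± 416) rose.

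**Figure D1:**
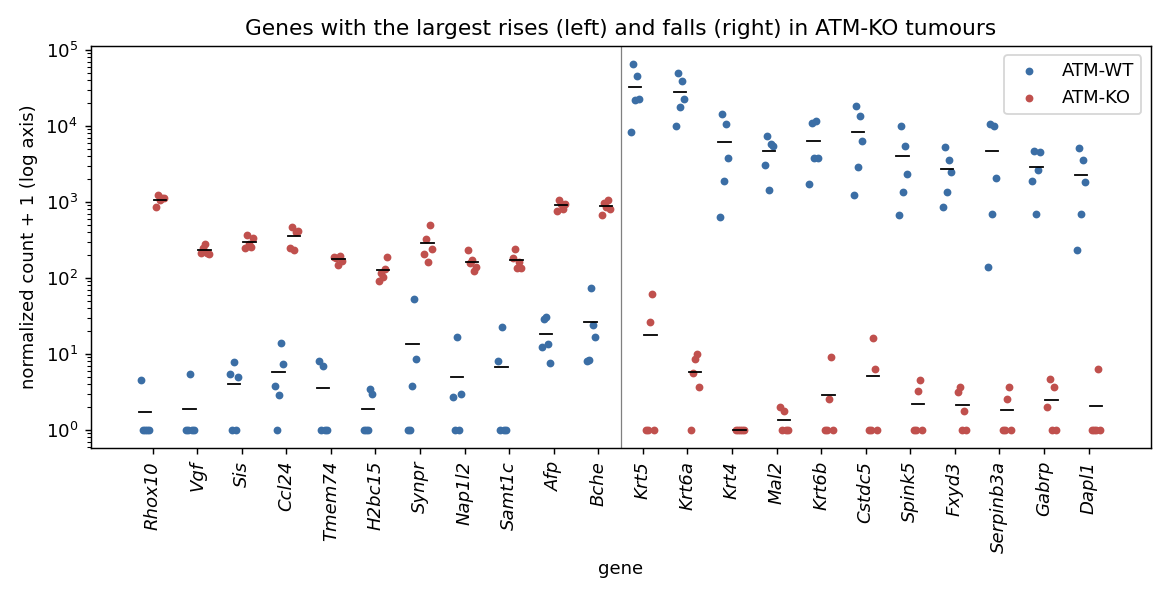
Normalized count + 1 on a log axis for 22 of the genes with the largest rises or falls, one point per library (5 ATM-WT in blue, 5 ATM-KO in red) with the group mean as a black line. No ATM-KO point of the 11 falling genes overlapped the ATM-WT points, and Krt4 was listed at 0 in all 5 ATM-KO libraries.

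The genes with the largest rises were of mixed kinds and low in ATM-WT. They included Rhox10 (9.62 ± 0.44), Vgf (7.36 ± 0.52), Sis (6.66 ± 0.60), Ccl24 (6.38 ± 0.60), Tmem74 (6.28 ± 0.66), H2bc15 (6.25 ± 0.52), Synpr (5.91 ± 0.93), Nap1l2 (5.90 ± 0.69), Samt1c (5.88 ± 0.84), Afp (5.79 ± 0.36) and Bche (5.58 ± 0.51). Rhox10 is a homeobox gene of an X-linked cluster used in the germline, Afp encodes alpha-fetoprotein, and Vgf encodes a neuropeptide precursor. Rhox10 averaged 0.701 ± 1.57 in ATM-WT and 1073 ± 146 in ATM-KO, and Afp 17.6 ± 10.4 and 904 ± 126. Rhox10, Samt1c and H2bc15 each belong to families with close copies, which share reads. In the list of transition regulators, the epithelial members Epcam (from 6852 ± 2811 to 50.04 ± 12.01) and Cldn4 (from 4796 ± 1608 to 251 ± 58.1) fell. Of all transition regulators 10 of 25 tested members rose and 9 fell (10 and 9 adjusted over the list alone), with a median of 0.27, a mean of -1.49 and a camera direction of down, so the signs differ. The signs also differ between median, mean and camera direction for chemokines, end joining, NRF2 and endothelial genes, none of them called by camera. The transition list was not called by camera (adjusted p = 0.80, and adjusted p = 0.95 with an estimated correlation). Fry called the transition list lower (adjusted p = 0.0024).

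Markers of several other cell types were called lower by camera. Of fibroblast markers 0 of 18 tested members rose and 14 fell (0 and 14 adjusted over the list alone), with a median of -1.90. The fibroblast list had camera adjusted p = 2.44e-04, and adjusted p = 0.71 with an estimated correlation. Dpt fell from 4549.6 ± 3702 to 113 ± 44.7 and the chemokine gene Cxcl12 from 3964 ± 2047 to 687 ± 240.0. Among matrix genes 2 of 29 tested members rose and 18 fell (2 and 19 adjusted over the list alone), with a median of -1.30. The matrix list had camera adjusted p = 0.0023, and adjusted p = 0.78 with an estimated correlation. The gelatinase genes Mmp9 (from 2794 ± 1025 to 477 ± 164) and Mmp2 (from 12107 ± 7539.5 to 1581 ± 479) fell and the inhibitor gene Timp1 (from 2968 ± 1134 to 10958 ± 1244) rose. Of mast cell and eosinophil markers 0 of 9 tested members rose and 8 fell (0 and 8 adjusted over the list alone), with a median of -4.50. The mast cell list had camera adjusted p = 2.48e-04, and adjusted p = 0.50 with an estimated correlation. A falling member was Tpsb2 (from 256 ± 194 to 1.46 ± 0.768). Of neutrophil markers 1 of 15 tested members rose and 8 fell (1 and 9 adjusted over the list alone), with a median of -1.28. The neutrophil list had camera adjusted p = 0.015, and adjusted p = 0.71 with an estimated correlation. Falling members included S100a8 (from 692 ± 74.1 to 253 ± 124) and Ltf (from 3415 ± 2564 to 10.1 ± 13.8). Ltf is also made by epithelia. Endothelial markers were not called, at 1 higher and 3 lower of 19, although Flt1 (from 477 ± 95.8 to 986 ± 67.8) rose and Rgs5 (from 1248 ± 160.1 to 461 ± 72.9) fell. Macrophage markers gave 1 higher and 4 lower of 24, where Arg1 (from 5913 ± 2779 to 1194 ± 319) and Cd14 (from 1678 ± 545 to 476 ± 60.1) fell. Not called either were skeletal muscle markers (0 higher and 1 lower of 20), adipocyte markers (2 higher and 2 lower of 9), nerve and Schwann cell markers (1 higher and 4 lower of 10), red blood cell markers (4 higher and 1 lower of 6).

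Replication and mitosis genes rose together in ATM-KO. Of DNA replication and E2F target genes 31 of 34 tested members rose and 1 fell (31 and 2 adjusted over the list alone), with a median of 0.96. The replication list had camera adjusted p = 3.80e-11, and adjusted p = 0.50 with an estimated correlation. Of G2/M and mitosis genes 28 of 30 tested members rose and 0 fell (28 and 0 adjusted over the list alone), with a median of 0.96. The mitosis list had camera adjusted p = 3.80e-11, and adjusted p = 0.54 with an estimated correlation. Cdc45 (from 358 ± 35.2 to 1043 ± 135), a helicase cofactor, Mcm4 (from 1143 ± 197 to 2840.1 ± 346), a helicase subunit, the cyclin gene Ccna2 (from 1891 ± 269 to 5152 ± 299) and the mitotic kinesin gene Kif4 (from 469 ± 70.3 to 1761 ± 134) all passed. Homologous recombination and Fanconi genes followed, where 20 of 34 tested members rose and 1 fell (20 and 1 adjusted over the list alone), with a median of 0.71. The recombination list had camera adjusted p = 2.90e-05, and adjusted p = 0.51 with an estimated correlation. A rising member was Fancb (from 146 ± 45.8 to 673 ± 97.2). Of checkpoint kinase genes 11 of 24 tested members rose and 3 fell (11 and 4 adjusted over the list alone), with a median of 0.39. The checkpoint kinase list had camera adjusted p = 0.025, and adjusted p = 0.71 with an estimated correlation. Topbp1 (from 1522 ± 148 to 2833 ± 194), an activator of ATR, and Mdc1 (from 950.1 ± 121 to 1689 ± 160.4) rose. Mdm4 (from 2518 ± 645 to 1092 ± 86.4) fell. The call of this list was lost without ATM-WT library A1 (median 0.33, adjusted p = 0.074) or A3 (median 0.30, adjusted p = 0.058, range over its alternatives 0.013 to 0.074). End joining genes were not called, with 5 higher and 6 lower of 20. Among them Xrcc6 (from 784 ± 121 to 1509 ± 109) and Parp1 (from 1246 ± 91.4 to 1976 ± 96.00) rose. p53 targets were split, 8 higher and 9 lower of 28, with Perp (from 11550.5 ± 8683 to 932 ± 254), also a desmosome gene, Trp53inp1 (from 1141 ± 325 to 476 ± 31.05) and Phlda3 (from 3020.0 ± 483 to 1606 ± 229) lower and the G2 gene Gtse1 (from 274 ± 42.3 to 941 ± 62.6) higher.

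**Figure D2:**
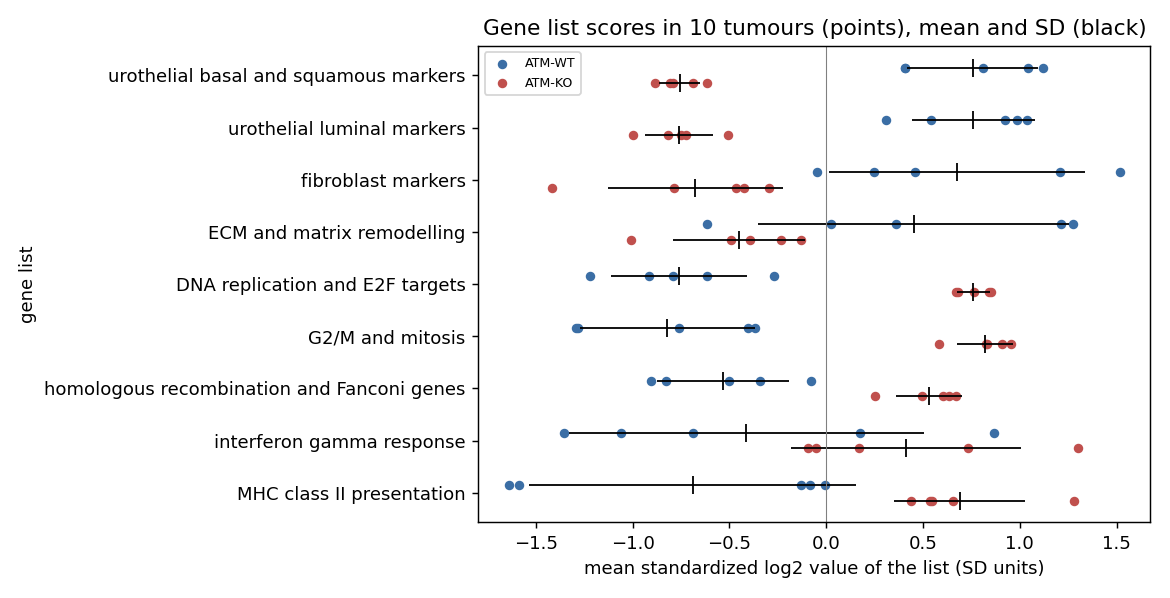
Mean standardized log2 value of 9 gene lists (x axis, SD units), one point per library (ATM-WT blue, ATM-KO red), with group mean and SD in black. The libraries of the genotypes overlapped for the matrix and interferon gamma lists and were apart for the other 7.

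Several immune lists were higher in ATM-KO, and some calls depended on ATM-WT libraries A2 and A4, which had the lowest scores of the MHC class II, checkpoint and cytotoxic lists. Among ATM-WT libraries, A2 and A4 also had the lowest fibroblast, matrix, macrophage and T cell scores and the highest basal and squamous scores. By the rough estimate A2 was shallow (8.82 M reads) but A4 was not (25.4 M), so low depth is not shared by both libraries. Both listed the most genes at 0. Whether this sparseness or cell content lies behind these calls cannot be told apart. Of type I interferon response genes 12 of 30 tested members rose and 1 fell (12 and 1 adjusted over the list alone), with a median of 0.53. The type I interferon list had camera adjusted p = 0.0016, and adjusted p = 0.71 with an estimated correlation. Rising members included Bst2 (from 2863 ± 1234 to 9284 ± 1282) and Ifih1 (from 510.5 ± 105 to 1253 ± 283). In the MHC class II list 9 of 11 tested members rose and 0 fell (11 and 0 adjusted over the list alone), with a median of 1.05. The class II list had camera adjusted p = 0.0022, and adjusted p = 0.71 with an estimated correlation. Rising members included H2-Ab1 (from 9611 ± 4532 to 18706 ± 2989) and H2-DMa (from 944 ± 313 to 2039 ± 255). Without A2 and A4, 5 class II members rose, the median was 0.53 (adjusted p = 0.0077, range over its alternatives 5.51e-04 to 0.013), and H2-Ab1 changed by 0.53, against 1.11 with all libraries. Of dendritic cell markers 10 of 17 tested members rose and 1 fell (12 and 1 adjusted over the list alone), with a median of 1.06. The dendritic cell list had camera adjusted p = 0.0018, and adjusted p = 0.56 with an estimated correlation. Rising members included Itgax (from 857 ± 154 to 2657 ± 367) and Flt3 (from 36.2 ± 28.96 to 419 ± 32.4). In the class I list 11 of 21 tested members rose and 1 fell (11 and 1 adjusted over the list alone), with a median of 0.38. The class I list had camera adjusted p = 0.0095, and adjusted p = 0.71 with an estimated correlation. Rising members included Tap2 (from 1427 ± 353 to 3229 ± 446) and Psmb8 (from 2978 ± 801 to 6084 ± 1517). Of interferon gamma response genes 10 of 28 tested members rose and 0 fell (9 and 0 adjusted over the list alone), with a median of 0.53. The interferon gamma list had camera adjusted p = 0.0095, and adjusted p = 0.84 with an estimated correlation. Of cytosolic sensing genes 8 of 17 tested members rose and 1 fell (9 and 2 adjusted over the list alone), with a median of 0.44. The sensing list had camera adjusted p = 0.018, and adjusted p = 0.71 with an estimated correlation. Rising members included Aim2 (from 126 ± 76.6 to 519.8 ± 57.5). Of checkpoint and costimulator genes 8 of 22 tested members rose and 1 fell (8 and 1 adjusted over the list alone), with a median of 0.45. The immune checkpoint list had camera adjusted p = 0.019, and adjusted p = 0.71 with an estimated correlation. Rising members included Tnfrsf9 (from 862 ± 496 to 3369 ± 375) and Lag3 (from 124 ± 39.8 to 459 ± 206). Of cytotoxic and NK markers 5 of 19 tested members rose and 1 fell (4 and 1 adjusted over the list alone), with a median of 1.25. The cytotoxic list had camera adjusted p = 0.021, and adjusted p = 0.71 with an estimated correlation. Rising members included Gzma (from 139 ± 91.7 to 713 ± 354) and Klra4 (from 48.5 ± 25.1 to 373 ± 38.6). Without A2 and A4 the calls of 5 of these lists were lost. For class I adjusted p = 0.062 (range over its alternatives 0.0011 to 0.23), while the median was 0.39 and so did not shrink. For interferon gamma the median was 0.25 (adjusted p = 0.25, range over its alternatives 2.48e-04 to 0.25), and for sensing 0.32 (adjusted p = 0.11, range over its alternatives 0.0055 to 0.11). For checkpoints it was 0.22 (adjusted p = 0.20, range over its alternatives 0.0054 to 0.20), and for cytotoxic markers 0.47 (adjusted p = 0.20, range over its alternatives 0.0046 to 0.20). Without library A2 alone, the checkpoint (median 0.30, adjusted p = 0.052) and cytotoxic (median 0.52, adjusted p = 0.079) calls were lost. The interferon gamma median was 0.35 without ATM-WT library A4, 0.83 without A5 and 0.33 without ATM-KO library A11, and its call was kept in each. T cell markers were not called (1 higher and 1 lower of 25), nor were B cell markers (2 and 1 of 10), where Blk (from 13.3 ± 5.91 to 238 ± 72.7) and Cd79a (from 20.8 ± 17.4 to 234 ± 22.98) rose. NK receptor ligands went both ways, 4 higher and 6 lower of 11, with the NKG2D ligand gene Raet1e (from 239.6 ± 19.9 to 25.4 ± 5.77) lower and Nectin3 (from 163 ± 105 to 687 ± 64.6) higher. Chemokines and NF-kB targets also went both ways (5 higher and 5 lower of 26, and 6 and 7 of 25), with Cxcl5 (from 4098 ± 1175 to 851 ± 464), Csf3 (from 83.5 ± 20.6 to 5.93 ± 4.80) and Ptgs2 (from 1229.5 ± 426 to 282 ± 106) lower and Nfkb2 (from 1765 ± 282 to 4365 ± 451) higher.

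Oxidative phosphorylation, sterol synthesis and unfolded protein genes were called higher, the first and last of these not after quantile normalization (adjusted p = 0.052 and 0.052). Of nuclear oxidative phosphorylation genes 17 of 32 tested members rose and 0 fell (18 and 0 adjusted over the list alone), with a median of 0.35. The oxidative phosphorylation list had camera adjusted p = 5.90e-04, and adjusted p = 0.71 with an estimated correlation. Rising members included Cox7b (from 2587 ± 411 to 5191 ± 623) and Cycs (from 2823 ± 356 to 5029 ± 495). Of sterol synthesis genes 11 of 20 tested members rose and 0 fell (11 and 0 adjusted over the list alone), with a median of 0.51. The sterol list had camera adjusted p = 0.0016, and adjusted p = 0.71 with an estimated correlation. Rising members included the regulator gene Srebf2 (from 3296 ± 431 to 8034 ± 958) and the synthase gene Fdps (from 1493 ± 306 to 3440.4 ± 527). In the unfolded protein list 12 of 23 tested members rose and 3 fell (14 and 3 adjusted over the list alone), with a median of 0.40. The unfolded protein list had camera adjusted p = 0.0028, and adjusted p = 0.54 with an estimated correlation. Rising members included Creld2 (from 875 ± 92.7 to 2773 ± 249) and the chaperone gene Hsp90b1 (from 12804 ± 683 to 23922 ± 2816). Hypoxia and glycolysis genes were not called (7 higher and 5 lower of 26), although Pgk1 (from 22811 ± 4120.2 to 59651 ± 3031) rose. NRF2 targets were not called by camera (8 and 6 of 23), with Txn1 (from 5636 ± 1201 to 13909 ± 982) higher and Gclc (from 1139 ± 168 to 606 ± 26.2) lower. Fry (adjusted p = 0.0020) and the exact permutation test of list scores (adjusted p = 0.026) called NRF2 targets higher.

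Of the 4 lists fixed as signs of RNA quality, histones were called higher by camera, fry and the exact permutation test of list scores, and ribosomal proteins by camera alone. RNA quality is not given in the deposited table. Of histone genes 8 of 12 tested members rose and 1 fell (8 and 1 adjusted over the list alone), with a median of 2.06. The histone list had camera adjusted p = 0.0045, and adjusted p = 0.54 with an estimated correlation. Histone genes have near-identical copies, which makes single values uncertain. The list holds replication-dependent histones, so its rise is not independent of that of the replication genes. Of ribosomal protein genes 9 of 34 tested members rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 0.22. The ribosomal list had camera adjusted p = 0.018, and adjusted p = 0.88 with an estimated correlation. For ribosomal proteins the fry adjusted p was 0.22 and the exact permutation adjusted p 0.39, and ATM-WT library A2 scored above every ATM-KO library. Without A2 and A4, 22 members rose and the median was 0.45, and without A2 alone it was 0.34. The ribosomal call was lost without ATM-WT library A1 (median 0.09, adjusted p = 0.22) or A3 (median 0.19, adjusted p = 0.058, range over its alternatives 4.88e-06 to 0.99). Not called were mitochondrially encoded genes (0 higher and 1 lower of 13) and immediate early and dissociation stress genes (5 higher and 5 lower of 19).

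In all, camera with a preset correlation called 17 lists higher and 7 lower of 42, and 0 with an estimated correlation, where 3 had an unadjusted p under 0.05. Several lists share members, such as Col1a1 in fibroblast and matrix and Psmb8 in class I and interferon gamma, so their calls are not independent. After quantile normalization the calls of 7 lists were lost. Medians were as large or larger for interferon gamma, 0.54 (deposited scaling 0.53, adjusted p = 0.056), sensing, 0.61 (deposited scaling 0.44, adjusted p = 0.053), and checkpoint kinase genes, 0.53 (deposited scaling 0.39, adjusted p = 0.052). They were smaller for class I, 0.30 (deposited scaling 0.38, adjusted p = 0.23), oxidative phosphorylation, 0.26 (deposited scaling 0.35, adjusted p = 0.052), unfolded protein, 0.32 (deposited scaling 0.40, adjusted p = 0.052), and ribosomal genes, 0.03 (deposited scaling 0.22, adjusted p = 0.99). These medians include the shift of all tested genes to a median of 0.15 in that setting. With a mean of at least 50, the cytotoxic (median 1.04, adjusted p = 0.10) and histone (median 1.90, adjusted p = 0.18) calls were lost. Without ATM-WT library A3, skeletal muscle markers were called higher (median 2.04 against 1.19 with all libraries, adjusted p = 0.046, range over its alternatives 0.046 to 0.98). An exact permutation test of list scores called 15 lists and fry 26. Of the lists camera called, fry did not call ribosomal proteins or interferon gamma genes (adjusted p = 0.15). The exact permutation test called neither of these nor the type I interferon, class I, immune checkpoint, checkpoint kinase, sterol, matrix, cytotoxic and neutrophil lists (adjusted p = 0.062 to 0.39 over all of them). Fry also called lists that camera did not, NRF2 targets higher and the transition list lower. Fry called the NK receptor ligand (adjusted p = 0.0050) and nerve (adjusted p = 0.018) lists lower too. Of the lists camera did not call, the exact permutation test called NRF2 targets alone. Other splits of the 10 libraries gave a median of 15 camera calls, so a single call of this kind is weak evidence by itself. The total count of changed genes carries more. Counts of members are to be read against all 16517 tested genes, of which 3649 were higher and 4017 lower. The counts of higher cytotoxic (5 of 19) and ribosomal (9 of 34) members lie near that share of higher genes.

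Genes were placed on chromosomes by symbol through GENCODE M21. Medians were highest on chromosome X (0.47, 225 higher and 74 lower of 500 genes) and lowest on chromosome 6 (-0.37, 75 higher and 326 lower of 813 genes). Camera also called chromosome 15 (0.33, 255 higher and 120 lower of 660 genes), chromosome 14 (0.29, 191 higher and 93 lower of 545 genes) and chromosome 3 (0.24, 281 higher and 170 lower of 831 genes) higher. With an estimated correlation adjusted p = 0.0023 for chromosome 6 and 0.0055 for X, and the other 3 calls were lost (adjusted p = 0.17, 0.12 and 0.19 for 15, 14 and 3). At the preset correlation, chromosomes 6, 15 and X were called in all 22 settings, the main one included. The eBayes and sample weight settings among them do not enter camera, so they could not change these calls. The chromosome 3 call was lost with no filter on low values (adjusted p = 0.20), without A2 and A4 (0.073) and without library A2 (0.064), A12 (0.063) or A13 (0.051). The chromosome 14 call was lost with no filter (0.054), and chromosome 5 was called lower with a mean of at least 50 (0.038) and after quantile normalization (0.049). As many chromosomes were called in 12 of 100 splits of the libraries, so the count of 5 does not exclude chance.

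**Figure D3:**
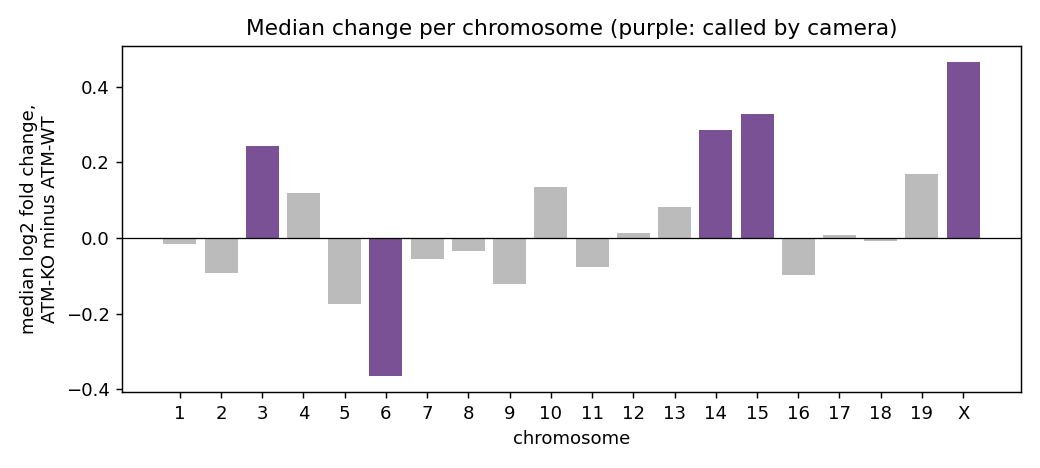
Median log2 fold change (ATM-KO minus ATM-WT) of the tested genes of each chromosome, as bars from 0, purple where camera with a preset correlation called the chromosome. The bars range from -0.37 on chromosome 6 to 0.47 on X.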

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

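Dixon's ratio was computed in each group of 5 for named genes, list scores and library measures. It singled out 33 of 464 groups (7.11%), where chance gives about 1 in 20, and no cause of any single value was tested.

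The value was the only one above 0 of its group for Rhox10 in ATM-WT library A1 (3.51, others listed at 0), Vgf in ATM-WT library A3 (4.43, others listed at 0), Dapl1 in ATM-KO library A14 (5.35, others listed at 0), H60c in ATM-KO library A11 (2.52, others listed at 0), Cxcl15 in ATM-KO library A12 (4.62, others listed at 0) and Cfd in ATM-WT library A3 (223, others listed at 0). It stood above the other libraries for H2-Oa in ATM-KO library A11 (123, others 52.1 to 61.5), Icam1 in ATM-KO library A11 (503, others 291 to 328), Uhrf1 in ATM-WT library A2 (1744, others 1285 to 1344), Pgam1 in ATM-KO library A11 (30464, others 26467 to 27277), Ocln in ATM-KO library A14 (10.8, others 6.39 to 7.09), Cd79a in ATM-KO library A12 (274, others 219.7 to 229), Cma1 in ATM-WT library A3 (226, others 68.6 to 92.2), Mbp in ATM-WT library A1 (1198, others 844 to 871), Hspb1 in ATM-KO library A14 (5439.9, others 4388 to 4659) and Rpl10 in ATM-KO library A15 (37709, others 34912 to 35557). It stood below them for Pdcd1lg2 in ATM-WT library A4 (16.6, others 36.9 to 46.5), Manf in ATM-WT library A4 (1854, others 2309 to 2412), Cldn4 in ATM-WT library A3 (1983, others 5136 to 5912), Bcl11b in ATM-KO library A15 (20.1, others 39.3 to 49.3), Cxcl12 in ATM-KO library A12 (293, others 689 to 918), H4c9 in ATM-WT library A1 (134, others 242 to 308) and H2ac4 in ATM-KO library A14 (11.6, others 25.6 to 29.96).

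Among list scores, in SD units, the highest stood apart for MHC class II presentation in ATM-KO library A11 (1.28, others 0.436 to 0.653), immune checkpoints and costimulators in ATM-KO library A11 (1.03, others 0.139 to 0.295), cholesterol and sterol synthesis in ATM-KO library A12 (1.22, others 0.181 to 0.48) and skeletal muscle markers in ATM-WT library A3 (1.39, others -0.802 to -0.331), and the lowest for immediate early and dissociation stress genes in ATM-WT library A3 (-0.834, others -0.0503 to 0.242). Among library measures the value stood apart for genes listed at 0 in ATM-KO library A12 (3602, others 2403 to 2641), value of one read in ATM-WT library A2 (2.46, others 0.828 to 0.995), estimated M (mega) reads in ATM-WT library A2 (8.82, others 20.6 to 25.4), genes near 1 read in ATM-WT library A4 (164, others 496 to 587) and ratio 1 to 10 reads in ATM-WT library A4 (0.877, others 2.73 to 3.47).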

How the results depend on the processing

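Leaving out ATM-WT libraries A2 and A4, and leaving out genes at 0 in one group, were chosen after seeing the data. No paired analysis was possible because the columns carry no sample number from the labels, and count models were not run because whole reads could not be recovered. Leaving out each library gave 3219 to 3791 genes higher, 3656 to 4064 lower, 22 to 24 lists, 4 to 5 chromosomes, and 64.1% to 68.9% of variance on the first component. Counts of genes stayed within 1.5 times the main count under every alternative run, and no gene changed from higher to lower. Without A2 and A4, 3242 of 3649 higher and 3417 of 4017 lower genes were called again. The chromosome count was 3 with no filter. List calls numbered 15 by exact permutation, 17 after quantile normalization, 19 without A2 and A4 and 0 with an estimated correlation, and the cause was not tested. The Atm difference, never past the threshold (limma adjusted p of at least 0.53), was 0.073 after quantile normalization and 0.060 without A2 and A4, and -0.21 to 0.12 with 1 library left out. The median of some uncalled lists changed sign, and the cause was not tested. With no filter on low values, it was -0.055 for chemokines. With a mean of at least 50, it was -0.199 for adipocyte markers. With upper-quartile scaling, it was -0.023 for endothelial and pericyte markers, -0.031 for immediate early and dissociation stress genes. With quantile normalization, it was 0.034 for NF-kB and TNF response, 0.060 for end joining genes, -0.047 for hypoxia and glycolysis, 0.109 for macrophage and monocyte markers. Without libraries A2 and A4, it was -0.198 for chemokines, -0.058 for epithelial-mesenchymal transition regulators, -0.069 for endothelial and pericyte markers, -0.117 for adipocyte markers, 0.064 for mitochondrially encoded genes. With 1 library left out, medians ranged from -0.115 to 0.263 for chemokines, from -0.072 to 0.169 for endothelial and pericyte markers, from -0.202 to 0.00049 for mitochondrially encoded genes, from -0.096 to 0.172 for hypoxia and glycolysis, from -0.295 to 0.126 for macrophage and monocyte markers, from -0.258 to 1.118 for adipocyte markers, from -0.087 to 0.863 for B and plasma cell markers, from -0.010 to 0.129 for immediate early and dissociation stress genes. Of named genes, 74 comparisons over all alternatives lost a call and 19 gained one, and 0 turned direction apart from Atm, whose changes of sign are given above. The shallow library A2 limits the precision of low genes.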

Other observations

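The 11 lists in this part, and the tests of lineage, cell type share, the mesenchymal genes and the epithelial genes without A2 and A4, were chosen after the results were seen. All 25 of 25 epithelial junction and keratin genes fell, with a median of -6.03. The most abundant left in ATM-KO were Jup (2380.5 ± 115), Krt18 (1709.7 ± 402) and Spint1 (777 ± 68.9). Single genes of unrelated lineages were high in ATM-KO, such as Cdh15, a muscle cadherin (262 ± 68.3 to 9134 ± 1571), Uchl1 (235 ± 126 to 5397 ± 473) and Tubb3 (1193 ± 463 to 5098 ± 564), both used by neurons. The remaining lists gave, as members tested, 1 higher and 14 lower of 21 for imprinted genes, 4 higher and 0 lower of 12 for leukocytes, 5 higher and 2 lower of 9 for neural genes, 4 higher and 2 lower of 6 for muscle, 1 higher and 6 lower of 8 for intestine, 3 higher and 4 lower of 8 for liver and endoderm, 3 higher and 1 lower of 7 for germline, 2 higher and 2 lower of 4 for pluripotency and 0 higher and 0 lower of 2 for melanocytes. No Y-linked gene of the list is in the table.

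For the low level of most epithelial genes in ATM-KO, a lower share of tumour cells alone would raise all other cell types alike. The fibroblast median was -1.90 (mean -1.79 ± 0.27, SE over genes) and the leukocyte median 0.56 (mean 0.49 ± 0.08, SE over genes). These values argue against a lower share with an unchanged mix of the other cells. They cannot speak to a lower share together with a changed mix, so the share of tumour cells stays open. Libraries A2 and A4 are not the whole cause, since 39 of 46 basal and luminal members still fell without them. No lineage list had more than 35.7% of its written members higher, which leaves cells of another origin in the ATM-KO tumours open. A shift of the tumour cells to mesenchymal genes is also open, because 10 of 17 mesenchymal genes rose and 1 fell (binomial p = 0.012), as such a shift predicts, but 8 rose and 2 fell without A2 and A4 (binomial p = 0.11). The binomial test counts genes of the same libraries as independent draws, so its p may be too small. Loss of ATM, the history of the knockout cells and a substituted line cannot be told apart here, since genotype and cell stock coincide.

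For the chromosome shifts, a few strong gene clusters are argued against, as chromosomes 6 and X were both called without genes changed by more than 2 log2 or with a mean under 100 (larger adjusted p = 2.87e-08). Medians over 50 neighbouring genes were 2.04 times as spread as in shuffled gene order, above all 100 shuffles, as different copy number would give. Pairs of libraries within a group already gave 1.26 to 1.54 in ATM-WT and 1.33 to 1.79 in ATM-KO. Neighbouring genes that vary together in any tumour may therefore give part or all of it. Differences between single libraries carry more noise per gene than those between group means, so these ratios are not on the same scale as 2.04. A candidate explanation is therefore copy number, not settled by these values. Chance was not excluded for the count of chromosomes, as 12 of 100 splits gave 5 or more and the highest other gave 8.

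For the rise of replication and mitosis genes, libraries A2 and A4 are not the cause, since 60 of 64 members rose without them, against 59 with them. Fewer fibroblasts would raise other cell types as much as the replication and mitosis genes, which had a mean of 0.94 ± 0.05 (SE over genes). The endothelial and pericyte mean was -0.0791 ± 0.14 SE and the macrophage mean -0.13 ± 0.16 SE. The leukocyte mean rose, but less, at 0.49 ± 0.08 SE. These values argue against fewer fibroblasts alone. These lists do not measure the share of tumour cells. The genotype, another property of the cell stock, the share of tumour cells and a difference in RNA quality stay open and were not tested. The histone list was fixed as a sign of RNA quality. Its genes are replication-dependent, so its rise is not independent of the rise being explained. Of the other lists fixed as such signs, ribosomal proteins were called by camera alone. The mitochondrially encoded (camera adjusted p = 0.90) and immediate early (camera adjusted p = 0.77) lists were not called.

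The count of changed genes argues against chance, at 7666 against at most 3 in the other splits (1 of 100 splits drawn from 126, the real one included). The other splits mix the genotypes, so the genotype difference adds to their spread and lowers their counts. Only the rank of the real split therefore counts, not the size of the gap. For lists, 4 of 100 splits called 24 or more, a share under 0.05, but the highest other split also called 24, and such splits still carry part of the genotype difference.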
